A study of Mus musculus with 9 samples.

How the data were processed

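Gene expression was measured by bulk RNA sequencing of 9 mouse prostate tumors of the genotype Pb-Cre+; Pten (fl/fl), 4 from control and 5 from exercise mice. Per the labels' protocols, total RNA was extracted with QIAzol and a miRNeasy kit, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, the tools were Trimmomatic, TopHat2 2.1.1, Cufflinks 2.2.1 with Cuffdiff, and featureCounts from Subread 2.0.0, with the mm10 build. Which tool made which table, the annotation, the strand setting and the filters are not given in the sources used here.

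The authors deposited a table of normalized counts rounded to whole numbers, a normalized score per gene and tumor and not raw counts. The authors also deposited a table of normalized FPKM values, fragments scaled by transcript length and library size. The method of normalization is not given in the sources used here. The upper quartiles of the normalized counts lay between 614 and 657 in all libraries while their totals ran from 17663000 to 102248000. Low values of control 3 skipped whole numbers, so the worth of 1 read was estimated per library as the spacing whose rounded multiples best matched the histogram of values from 1 to 60, a method tested on simulated reads. In control 3, 99.5% of values in that range lay on multiples of 3.79, which cover 25% of whole numbers, and in control 2 99.8% lay on multiples of 1.14. In the other libraries the spacing is below 1, so no whole number is skipped and the estimate rests on whole numbers that a pair of multiples share. These held 1.67 to 2.01 times the genes of their neighbors (median per library), where 2 is expected. Whole reads could not be recovered and no count model was used. Estimated depth was 24030000 to 26960000 reads. Counting error is not included in any value, and no interval was derived from the estimated depth.

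Values were analysed as log2(normalized count + 1), for genes with a value of at least 10 in at least 4 tumors (14818 of 24346). Fold changes are on this scale, which understates changes of low genes. Exercise was compared with control by limma 3.58.1 in R 4.3.3 (linear model, moderated variance with trend and robust settings, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as threshold. Before the data were examined, this design, 46 gene lists and the rule for named genes were fixed, with a count test planned for raw counts and limma for normalized values. Lists with at least 5 tested members (45 of 46) were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. Camera sets a list against all other genes, while fry asks only whether its members move on balance in 1 direction. The seminal vesicle list, with 4 tested members, was tested as a mean over 11 measured members by an exact permutation test, chosen after seeing the data.

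Named genes were Pten, the genes past the threshold or, since none passed, the 6 with the smallest unadjusted p in each direction with a group mean of at least 50, and 2 to 4 members with the smallest p of each list described. Predicted genes, unnamed clones and immunoglobulin or T cell receptor segments were skipped. Each value is a mean ± SD over 4 control and 5 exercise tumors, controls first, unless values per tumor are given. Gene positions are those of the GRCm38.p6 annotation, the build of mm10, matched by NCBI Gene ID. Transcript length and GC content were medians over GENCODE transcripts, available for 96.3% of tested genes. No 2 libraries were duplicates: the smallest median absolute log2 difference between a pair was 0.175.

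Alternatives were other scalings (trimmed mean of M values, upper quartile), other filters and pseudocounts, the FPKM table, each tumor left out, and replicate number as a block. Library weights and removal of transcript length or GC trends were added after seeing the data. Choice of the weights and trend removals aside, all of these were fixed beforehand. The FPKM fits had their own filter, an FPKM of at least 1 in at least 4 tumors. They covered 11907 genes and 43 lists, so a list median there may be over fewer members than the main one. The gene test was checked on simulated values with 200 changed genes, and the list test on 1 shifted list, where it called 1 of 45 lists. Values were simulated independently for each gene, so this check does not test false calls of lists whose members move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.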

Results

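Bulk RNA sequencing profiled 9 prostate tumors from mice in which the tumor suppressor Pten is deleted in prostate epithelium by a probasin-driven Cre recombinase. Of these tumors, 4 came from control mice and 5 from mice with voluntary wheel running, collected at the end of the study. The comparison asks how gene expression in these tumors differs between runners and controls. The values are normalized counts for 24346 genes, of which 14818 passed the filter on low values and were tested. Total normalized counts per library were 23699800, 30642400, 102248000 and 20977100 in control 1 to 4. They were 21752700, 22651200, 24968500, 19059700 and 17663000 in exercise 1 to 5. The worth of 1 read, estimated from the spacing of low values, was 0.735 to 1.14 normalized counts in 8 libraries and 3.79 in control 3. The totals divided by this worth gave an estimated 24030000 to 26960000 reads per library. By this estimate control 3 had about as many reads as the others, and its values were scaled up. Single low values are coarsest in that library. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples.

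The tumors differed most in genes of the secretory epithelium of the prostate lobes and the seminal vesicle, and these differences did not follow the groups cleanly. Svs2, a major seminal vesicle secretory protein, stood at 1776010 normalized counts in exercise 1, 914468 in exercise 3 and 1059220 in exercise 4. It stood at 13 in exercise 2, 18 in exercise 5 and 2 to 32 in the controls. Over the 11 measured genes of the seminal vesicle list, the mean log2(normalized count + 1) was 1.49 ± 0.72 (SD, n = 4) in controls and 9.28 ± 6.79 (SD, n = 5) in exercise tumors. An exact two-sided permutation test of the 9 tumors gave p = 0.0714 for this difference of 7.79, where the smallest possible p is 0.0079, and the difference was 5.99 without exercise 1. Svs4 and Svs5, from the same gene cluster on chromosome 2, followed Svs2, with 569682 and 729640 normalized counts in exercise 1. Sbp, the spermine-binding protein of the ventral prostate, was chosen after its values were seen and had another pattern. It stood at 959151 to 5546870 in the controls and at 2028780 in exercise 2, but at 2591 in exercise 1, 137 in exercise 3, 518186 in exercise 4 and 20724 in exercise 5. Sbpl and Spink1, also named after their values were seen, were likewise lowest in exercise 1, 3 and 5. Of the 20 tested members of the prostate lobe secretory list, 9 had a higher and the rest a lower mean in exercise tumors. None passed over all genes tested, while 7 higher and 8 lower passed adjusted over the list alone. The list as a whole was not called by camera, a competitive gene set test (adjusted p = 0.517, median log2 fold change −0.62). Without control 3 its median was −0.09 (0.812). Members that move in opposite directions cancel in camera. Fry's mixed test, for change in either direction, gave this list adjusted p = 0.0219, and 15 of the 45 lists passed that test. Only 4 seminal vesicle genes passed the filter, too few for camera, and 3 of them were higher adjusted over the list alone. With no filter camera at its preset correlation of 0.01 called the seminal vesicle list as higher (median 8.17, adjusted p = 0.00104). The members of this list were high in the same tumors, which that preset does not allow for. No estimated correlation was run for it. The labels name no lobe for any sample.

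**Figure D1:**
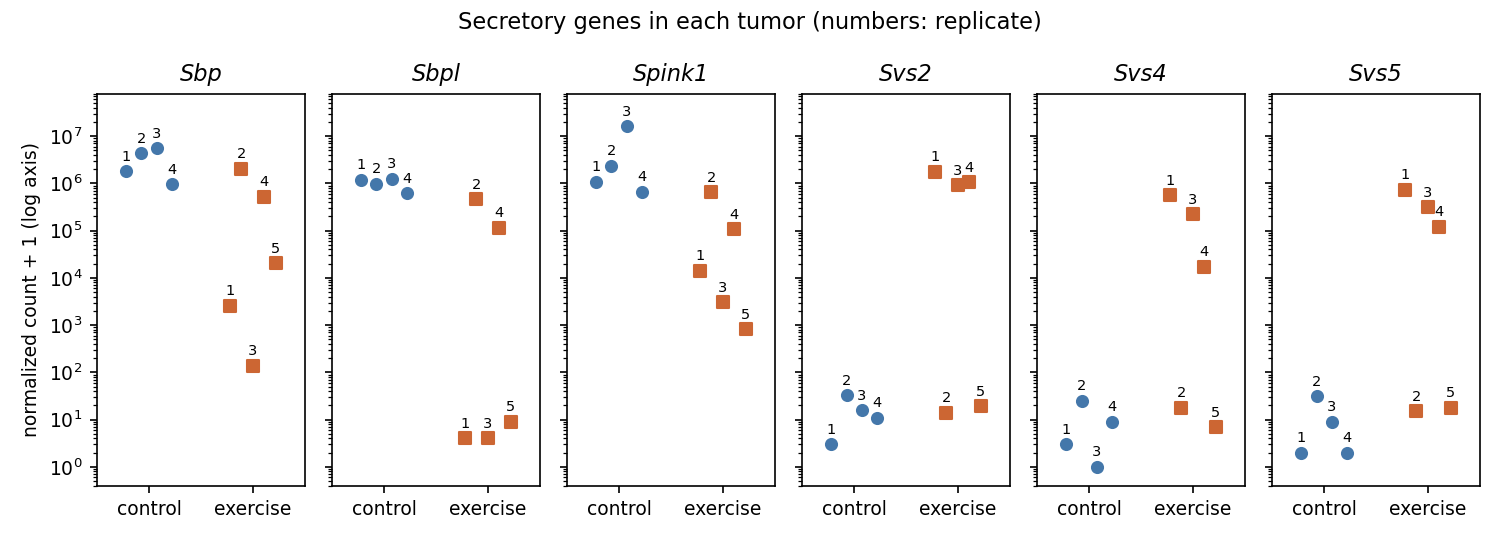
Normalized count plus 1, on a log axis, of 6 secretory genes in each tumor, controls as circles and exercise tumors as squares, with the replicate number beside each point. Svs2 lies at 914468 or above in exercise 1, 3 and 4 and at 32 or below in the other tumors, while Sbp lies at 959151 or above in the controls and in exercise 2.

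Principal components placed most exercise tumors on one side and control 3 far on the other. Component 1 held 54.9% of the variance of the log2 values and component 2 held 26.6%. On component 1 control 3 scored −192 and the other controls −77.5 to 8.40, while exercise 2 scored 0.484 and the other exercise tumors 46.4 to 97.9. Exercise 2 therefore lay within the range of the controls on this component. Its group is that of its label, which the values do not test, and group means and the counts without exercise 2 given below rest on it. The libraries also differed in a trend with transcript length. The Spearman correlation across genes between a library's deviation from the gene mean and transcript length was −0.386 in control 3, −0.300 in control 2, 0.068 in control 1 and 0.239 in control 4. The group means of this correlation were −0.09 ± 0.30 (SD, n = 4) in controls and 0.22 ± 0.17 (SD, n = 5) in exercise tumors. Genes are not independent replicates in such a correlation.

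**Figure D2:**
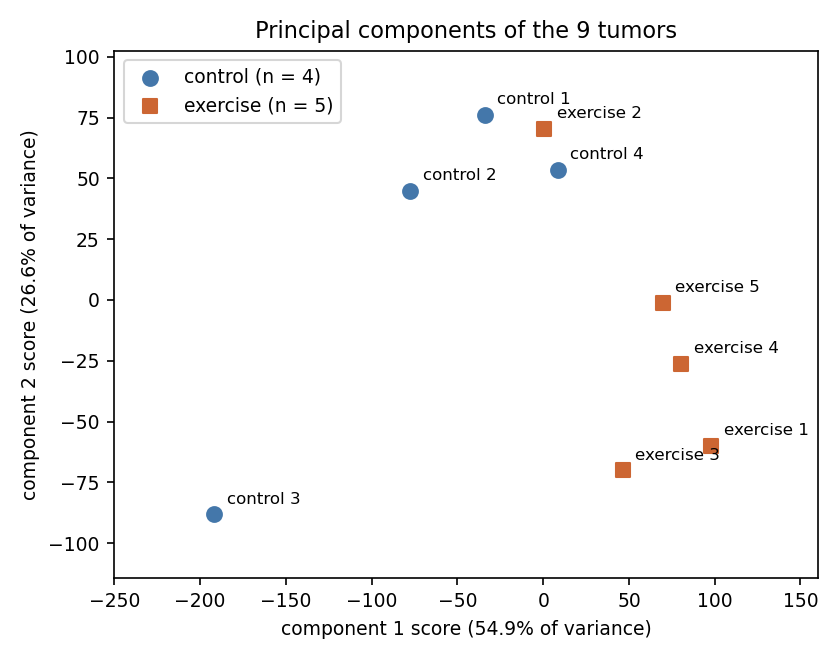
Scores of the 9 tumors on components 1 and 2 of the log2 values, controls as circles and exercise tumors as squares. Control 3 scores −192 on component 1, and exercise 2, at 0.484, lies within the range of the controls.

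Pten itself, the gene deleted in the epithelium, was detected in every library. Its normalized counts were 2074, 1880, 2126 and 1795 in control 1 to 4, and 2466, 1984, 3208, 2386 and 2526 in exercise 1 to 5. The means were 1969 ± 157 (SD, n = 4) in controls and 2514 ± 442 (SD, n = 5) in exercise tumors. The log2 fold change of 0.34 ± 0.18 (SE) did not pass the limma test (adjusted p = 0.225). It was −0.24 with the transcript length trend removed (adjusted p = 0.590) and 0.25 with library weights (adjusted p = 0.0196), both tried after seeing the data. Pten spans positions 32757577 to 32826160 of chromosome 19 in the GRCm38 (mm10) build. Both groups carry the deletion per the labels, and gene-level values include transcripts of cells without Cre, so the level does not test the labels.

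No gene passed limma's test at the adjusted threshold. The test, with Benjamini-Hochberg adjustment over 14818 genes, called 0 genes, and the smallest adjusted p was 0.130. At an unadjusted p under 0.05 there were 4087 genes, 2362 higher and 1725 lower in exercise tumors, where chance alone gives 741. Higher genes made up 57.8% of these, and 47.5% of the 3074 such genes in the FPKM values. Without exercise 2 the test called 1343 genes, 857 higher and 486 lower. No other left-out library gave a call, but the count at an unadjusted p was 2221 without control 2, 2290 without exercise 1, 2386 without exercise 4 and 2680 without exercise 5. In simulated data with the real spread of each gene, the test found 0% of genes changed by 1 on the log2 scale, 49% of those changed by 2 and 86.5% of those changed by 4.

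The 6 genes with the smallest p in each direction are named although they did not pass, each at adjusted p = 0.130. Higher in all 5 exercise tumors than in any control were Gas1, a cell surface protein of the hedgehog pathway, Hoxd11, a homeobox transcription factor, and Sema3c, a secreted semaphorin. Gas1 (chromosome 13, 60174405 to 60177535) was at 184 ± 51.3 normalized counts (SD, n = 4) in controls and 681 ± 202 (SD, n = 5) in exercise tumors. Sema3c (chromosome 5, 17574816 to 17730268) was at 185 ± 35.3 and 808 ± 273, and Hoxd11 (chromosome 2, 74679558 to 74687016) at 17.2 ± 4.27 and 76.6 ± 18.9. Their log2 fold changes were 1.87 ± 0.32, 2.04 ± 0.35 and 2.09 ± 0.35 (SE). Arhgef17, a Rho guanine nucleotide exchange factor, and Cacna1h, a T-type calcium channel, had log2 fold changes of 2.46 ± 0.46 and 2.40 ± 0.47. C1rb, a complement serine protease gene with a close paralog and hence an uncertain count, was at 1 to 4 in controls and at 7945, 31, 55208, 4674 and 348 in exercise 1 to 5. On the lower side stood Gpx3, the secreted glutathione peroxidase (chromosome 11, 54902854 to 54910387), with 26609 ± 7144 in controls and 9552 ± 2585 in exercise tumors. Agtr1a, an angiotensin II receptor gene (chromosome 13, 30336356 to 30382867), was at 1292 ± 454 and 359 ± 176. Adh6a, an alcohol dehydrogenase gene, was at 1058 to 2601 in controls and at 3 to 519 in exercise tumors, the 519 being exercise 2. Wfdc3, Krtap17-1 and Scgb2b15 had log2 fold changes of −5.23, −3.85 and −9.50. Scgb2b15 belongs to the large androgen-binding protein family of near-identical genes, so its count is uncertain. C1rb, Agtr1a and Wfdc3 are also members of the prostate lobe secretory list. Of the exercise tumors, exercise 2 was nearest the controls for Wfdc3 (147, the others 4 to 37) and Scgb2b15 (302, the others 0 to 2). All 12 genes passed without exercise 2, at adjusted p from 0.012 to 0.025 in limma.

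Markers of smooth muscle, vessels, nerves and fibroblasts were higher in exercise tumors as groups. Of 46 gene lists fixed beforehand, 45 could be tested, and camera with its preset correlation of 0.01 called 14. None of the 14 held with the correlation between genes estimated from the data, where each had adjusted p = 0.763 with an estimated correlation. The directional fry test also called 0. No member of any list passed the gene-wise test over all genes, so gene values below are given as levels. All 18 smooth muscle markers had a higher mean in exercise tumors, with a median log2 fold change of 1.66 (camera adjusted p = 2.69e-06, and 0.763 with an estimated correlation). Of these, 9 passed adjusted over the list alone. Myh11, the smooth muscle myosin heavy chain, was at 1448 ± 779 in controls and 14142 ± 9927 in exercise tumors, and Synm, the intermediate filament protein synemin, at 510 ± 86.4 and 2129 ± 1037. All 21 endothelial markers were on the higher side, with a median of 1.53 (adjusted p = 1.46e-06, and 0.763 with an estimated correlation), and 13 passed adjusted over the list alone. Among them Eng, a TGF-beta co-receptor of vessels, was at 267 ± 89.1 and 643 ± 206, and the receptor Tie1 at 79.0 ± 56.3 and 281 ± 130. The 16 nerve and Schwann cell markers had a median of 2.31 (adjusted p = 2.18e-05, and 0.763 with an estimated correlation), with 10 passing adjusted over the list alone. Nefl, a neurofilament chain, was at 0, 0, 0 and 6 in controls and at 212, 4, 99, 86 and 24 in exercise tumors. Cdh19, a cadherin of Schwann cells, was at 0 to 7 in controls and 17 to 47 in exercise tumors. Of the 28 fibroblast and matrix genes, 27 had a higher mean and the median was 1.07 (adjusted p = 2.85e-04, and 0.763 with an estimated correlation), while 0 passed adjusted over the list alone. Col6a1, a type VI collagen chain, was at 698 ± 596 and 2086 ± 1124, and Pdgfrb, a receptor of mesenchymal cells, at 117 ± 54.6 and 358 ± 188. The mean level of the fibroblast list was 9.83 in control 4, above exercise 2 at 9.18 and exercise 3 at 8.70. The mean level of the smooth muscle list was 9.36 in exercise 2 and 9.45 in exercise 5, next to 9.37 in control 1, and 11.1 to 11.6 in the remaining exercise tumors. Those remaining tumors, exercise 1, 3 and 4, were also the ones with seminal vesicle list means of 16.5, 14.1 and 11.7, against 2.13 and 2.04 in exercise 2 and 5. Their urothelial list means were 8.75, 8.80 and 9.07, against 6.17 and 7.06.

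**Figure D3:**
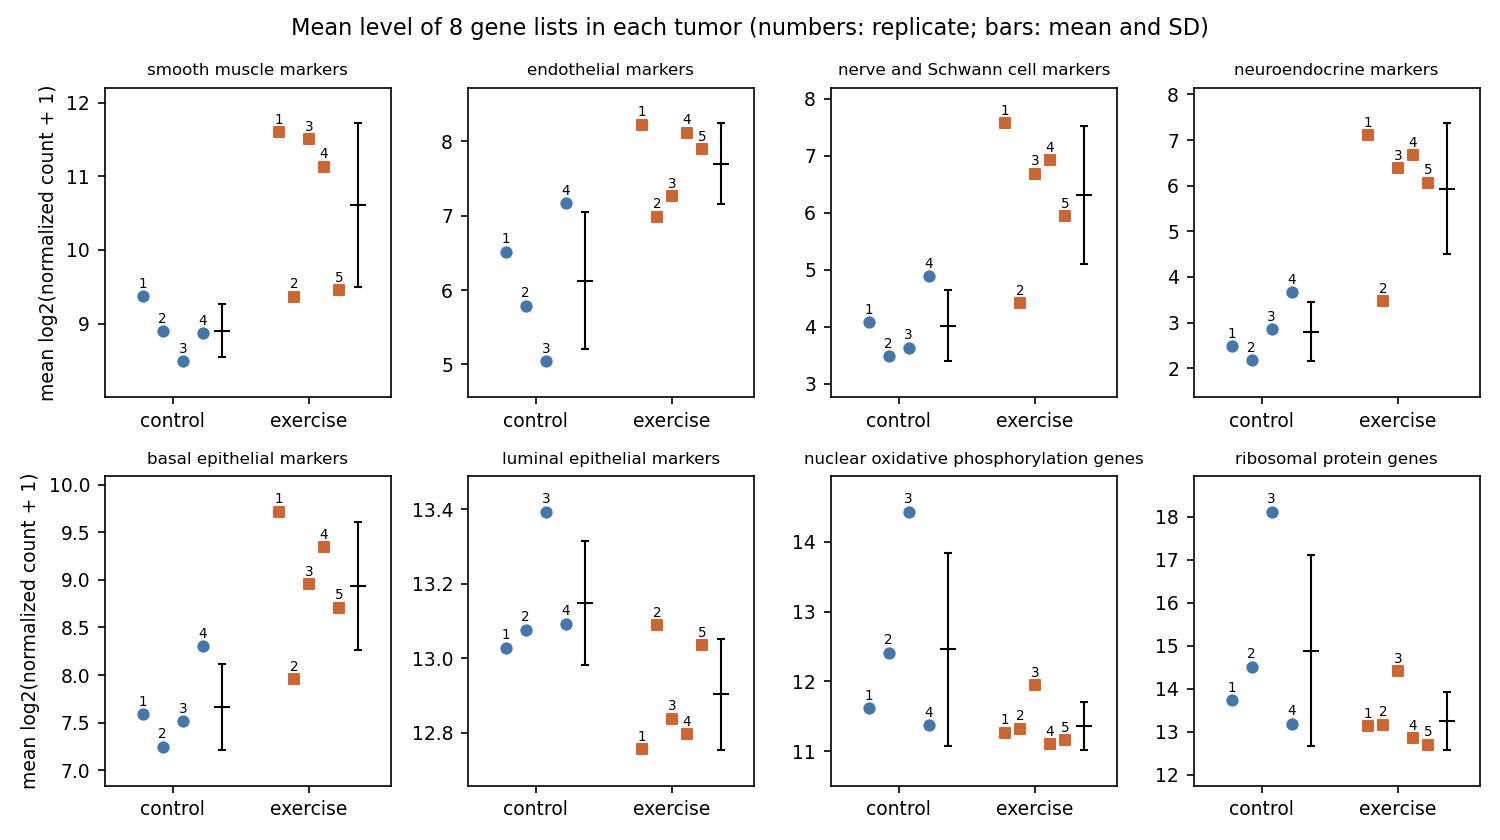
Mean log2(normalized count + 1) over the tested members of 8 gene lists in each tumor, controls as circles and exercise tumors as squares, with group mean and SD as bars. Control 3 is highest in the ribosomal protein list, at 18.1, and exercise 2 lies lowest of the exercise tumors in the neuroendocrine list, at 3.47.

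Basal epithelial and neuroendocrine markers were higher and luminal epithelial markers lower in exercise tumors, as levels in whole tumor tissue. All 15 tested neuroendocrine markers had a higher mean, with a median log2 fold change of 3.39 (camera adjusted p = 5.34e-07, and 0.763 with an estimated correlation), and 13 passed adjusted over the list alone. Their levels were low, so the fold changes depend on the pseudocount. In the FPKM values, with their own filter, the median was 1.01 with a pseudocount of 1 and 1.94 with 0.1. For basal markers it was 0.87 and 1.54. Ascl1, a neuroendocrine lineage transcription factor, was at 0, 0, 0 and 3 in controls and at 51, 3, 33, 65 and 67 in exercise tumors. Snap25, a synaptic vesicle fusion protein also made by nerves, was at 0, 0, 0 and 8, and at 267, 7, 144, 145 and 66. Exercise 2 was within the control range for both genes and, at a list mean of 3.47, below control 4 at 3.67. The nerve and Schwann cell list stood at 7.57, 4.41, 6.68, 6.92 and 5.93 in exercise 1 to 5 and at 3.48 to 4.88 in controls, where the neuroendocrine list stood at 7.10, 3.47, 6.39, 6.66 and 6.07 and at 2.18 to 3.67. Several of its members are also made by neurons. Of 16 basal markers 13 had a higher mean, the median was 1.53 (adjusted p = 0.00141, and 0.763 with an estimated correlation), and 7 passed adjusted over the list alone. Trp63, the basal cell transcription factor p63, was at 79.2 ± 21.4 and 311 ± 137, and Col17a1, a hemidesmosomal collagen, at 132 ± 94.6 and 530 ± 231. The mean level of the basal list was 9.71, 8.95 and 9.34 in exercise 1, 3 and 4, the tumors with high seminal vesicle and urothelial lists, and 7.95 and 8.71 in exercise 2 and 5. The basal keratin Krt15, chosen after its values were seen, was at 8725, 6530 and 6089 in these 3 tumors, and at 654 and 755 in exercise 2 and 5. The 18 luminal markers had a median of −0.31 (adjusted p = 0.0409, and 0.763 with an estimated correlation), with 0 passing adjusted over the list alone. Hoxb13, a homeobox gene of the prostate lineage, was at 21538 ± 12518 in controls and 5881 ± 4058 in exercise tumors, and the tight junction gene Cldn3 at 8109 ± 855 and 4883 ± 1473. The luminal call was lost without control 1, control 3, control 4, exercise 1, exercise 3 or exercise 4, with adjusted p of 0.0727, 0.0510, 0.0837, 0.0597, 0.0694 and 0.0569. The medians in these fits stayed between −0.36 and −0.26. Markers of the luminal progenitor-like state of Pten-null prostate were not called (median 0.66, adjusted p = 0.183, and 0.918 with an estimated correlation). At the preset correlation they were called as higher without control 3 (median 1.16, adjusted p = 0.00356) and without exercise 2 (1.08, 0.0192). They were also called in the FPKM values with a pseudocount of 1 (0.66, 0.0437) but not of 0.1. The same held with the length trend removed (0.90, 0.0400) and with library weights (1.86, 8.82e-05). Among them Kit, also a member of the mast cell list, was at 30.0 ± 26.5 and 295 ± 182, Krt4 at 1700 ± 1065 and 5669 ± 2671, and Clu at 71515 ± 21672 and 224189 ± 101277. The mast cell list stood at 6.87, 3.82, 6.49, 7.00 and 6.65 in exercise 1 to 5 and at 3.62 to 5.63 in controls.

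Oxidative phosphorylation, ribosomal protein, glycolysis and cholesterol biosynthesis genes were lower on average in exercise tumors. Control 3 lay above every other library in oxidative phosphorylation and ribosomal protein genes. The 36 nuclear oxidative phosphorylation genes had a median log2 fold change of −1.22 (camera adjusted p = 1.17e-06, and 0.763 with an estimated correlation). The 32 ribosomal protein genes, all with a lower mean, had a median of −1.63 (adjusted p = 1.46e-06, and 0.763 with an estimated correlation). Adjusted over the list alone 0 members passed in either. An unadjusted p under 0.05 was reached by 0 ribosomal protein genes and by 2 oxidative phosphorylation genes, which were lower. Exercise 3 had list means of 14.4 (ribosomal protein) and 11.9 (oxidative phosphorylation), above control 1 (13.7 and 11.6) and control 4 (13.2 and 11.4). Uqcrfs1, a complex III subunit, was at 3384, 5834, 16385 and 2683 in controls and at 1783 to 2951 in exercise tumors. Cytochrome c, Cycs, was at 31924 in control 3 and at 1884 to 6318 in all other tumors. Rpl3 and Rpl8, ribosomal proteins of the large subunit, were at 289000 and 268241 in control 3, against 12965 to 45063 and 10242 to 32128 elsewhere. Ribosomal protein, cytochrome c and lactate dehydrogenase genes have many processed pseudogenes, so their counts are uncertain. Without control 3 the medians were −0.42 for oxidative phosphorylation and −0.57 for ribosomal protein genes, and both lists were still called (adjusted p = 2.27e-05 and 2.73e-04). Both lists were also called after the transcript length trend was removed, with medians of −0.81 and −1.32. The 21 glycolysis genes had a median of −0.56 (adjusted p = 0.00457, and 0.763 with an estimated correlation), and 1 higher and 5 lower passed adjusted over the list alone. Pgam1, a phosphoglycerate mutase, was at 14208 ± 2832 and 6599 ± 2284, and Ldha, lactate dehydrogenase A, at 41346 ± 12092 and 17123 ± 5246. The 22 cholesterol biosynthesis genes had a median of −0.44 (adjusted p = 0.0115, and 0.763 with an estimated correlation), with 5 lower adjusted over the list alone. Insig1, a sterol-regulated brake on SREBP processing, was at 2522 ± 729 and 1228 ± 325, and Fdft1, squalene synthase, at 3723 ± 958 and 1987 ± 411. The cholesterol call was lost without exercise 3 (median −0.31, adjusted p = 0.0612).

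Developmental signaling, mesenchymal transition and dendritic cell lists were also higher in exercise tumors, while the other immune lists were not called at the settings used here. The 18 Wnt, Hippo and Notch target genes had a median log2 fold change of 0.87 (camera adjusted p = 0.0230, and 0.763 with an estimated correlation), with 6 higher adjusted over the list alone. Axin2, a direct Wnt target, was at 63.5 ± 47.4 and 421 ± 238, and the transcription factor Tcf7 at 11.8 ± 9.95 and 141 ± 122. This call was lost in the FPKM values, over the members that passed their own filter. The median there was 0.07 with a pseudocount of 1 (camera adjusted p = 0.306) and 0.13 with 0.1 (0.264). The mean level of the list was 8.22, 7.82 and 7.94 in exercise 1, 3 and 4, the tumors with high seminal vesicle and urothelial lists. It was 6.89 and 7.39 in exercise 2 and 5, and 5.95 to 7.05 in controls. The 18 mesenchymal transition genes had a median of 0.96 (adjusted p = 0.00459, and 0.763 with an estimated correlation), with 3 higher adjusted over the list alone. Zeb1, a transcription factor of that program, was at 172 ± 74.1 and 415 ± 123, and Itga5, the fibronectin receptor subunit, at 189 ± 172 and 591 ± 223. Fibroblasts express genes of this list too. Its mean level was highest in exercise 1, 4 and 5, at 8.91, 8.65 and 8.53, the tumors with the highest fibroblast and matrix list means, at 10.6, 10.2 and 10.3. In exercise 3 the 2 levels were 8.04 and 8.70. The 15 dendritic cell markers had a median of 0.80 (adjusted p = 0.0286, and 0.763 with an estimated correlation), with 0 passing adjusted over the list alone. Wdfy4, needed for cross-presentation, was at 105 ± 65.0 and 247 ± 100.02, and Fscn1, an actin bundler also made by other cells, at 68.5 ± 36.7 and 183 ± 86.0. The dendritic call was lost without control 1 (median 0.49, adjusted p = 0.183) and without exercise 3 (0.83, 0.0659). It was also lost in the FPKM values with their own filter (median 0.20, adjusted p = 0.368). Macrophage and monocyte markers had a median of 0.01 (adjusted p = 0.728). Within that list Arg1, arginase 1, was at 5337 to 10072 in controls and at 476, 5337, 301, 1230 and 1231 in exercise tumors. For Arg1, as for Sbp, exercise 2 lay within the control range and the other exercise tumors below it. The engulfment receptor Mertk was at 106 ± 59.1 and 403 ± 172. Adjusted over the list alone, 3 macrophage genes were higher and 1 lower. Medians were 0.51 for T cell and cytotoxic genes (adjusted p = 0.692), 0.47 for T cell checkpoint and regulatory genes (0.353), −0.24 for NK cell markers (0.725) and 0.65 for B and plasma cell markers (0.515). Without control 3 the T cell list was at 0.26 (0.545), the NK list at −0.08 (0.879), the B cell list at 0.39 (0.545) and the macrophage list at 0.22 (0.201), and without exercise 2 the B cell list was at 1.06. With all tumors the medians were 0.20 for neutrophil and granulocytic suppressor cell genes (0.905, and 0.92 with 0.0903 without control 3) and 1.54 for mast cell and eosinophil markers (0.105), a list called as higher without exercise 2 (2.32, 0.00333), with no filter (1.79, 0.0446), in the FPKM values (1.19, 0.0107) and with the length trend removed (1.71, 0.0400). With library weights, a fit that did not converge, the mast cell, T cell, checkpoint, B cell, macrophage, neutrophil and inflammatory lists were called as higher too. Antigen presentation genes (median −0.02, adjusted p = 0.765), interferon-stimulated genes (−0.04, 0.693) and inflammatory cytokine and NF-kB genes (0.03, 0.981) were close to 0. Without control 3 the inflammatory list was at 0.48 (0.187), the antigen presentation list at 0.11 (0.879) and the interferon list at 0.08 (0.718), and without exercise 5 the interferon list was called as lower (−0.43, 0.0195).

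**Figure D4:**
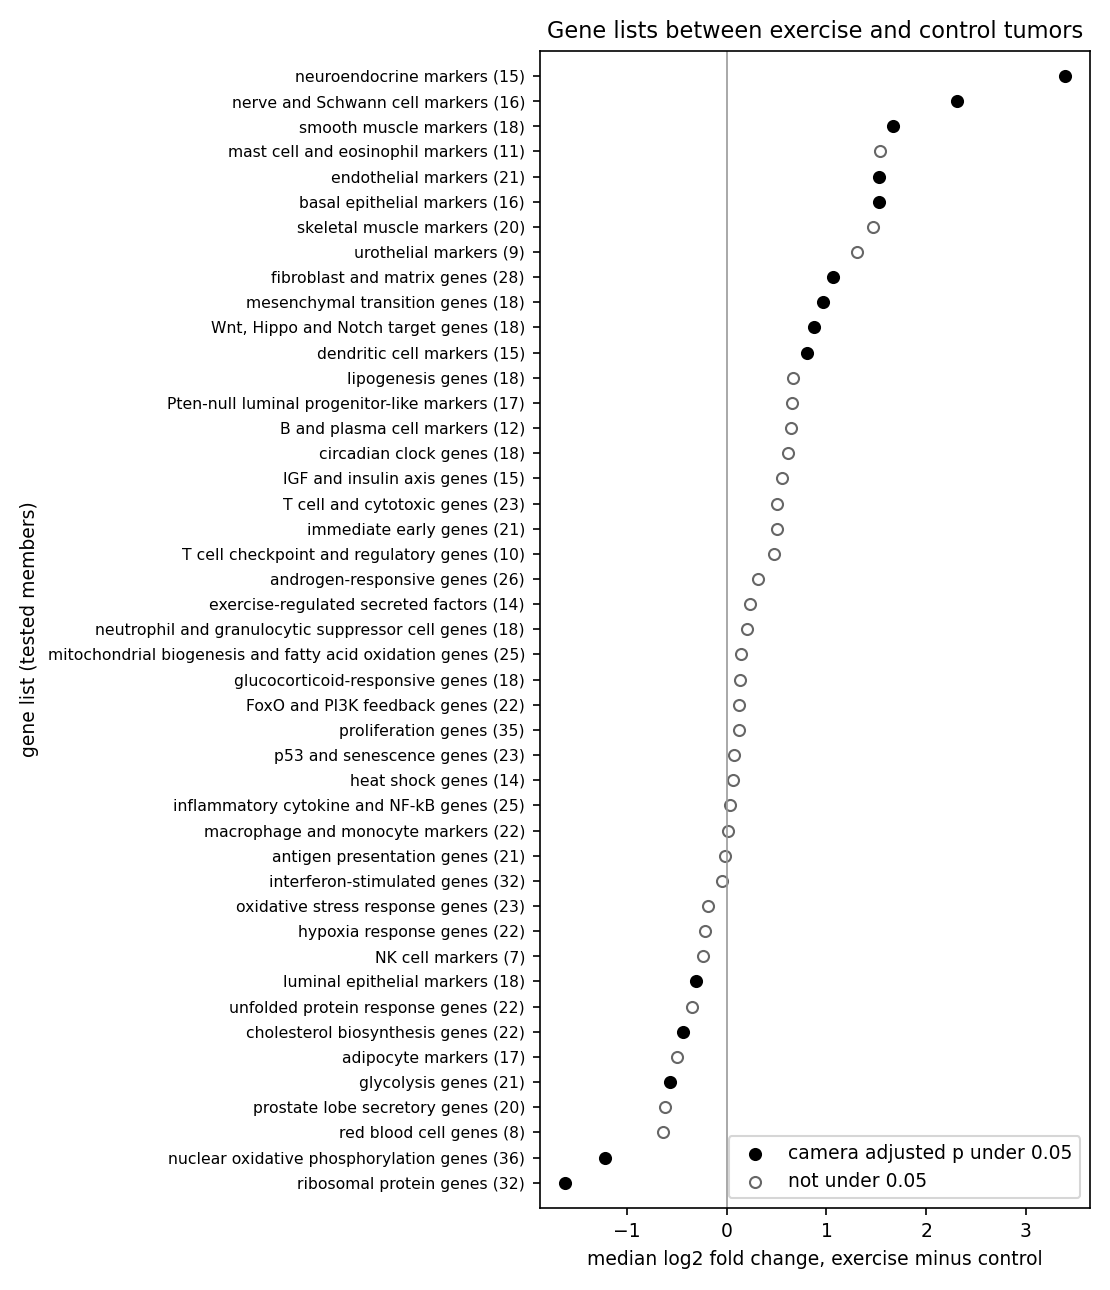
Median log2 fold change, exercise minus control, over the tested members of each of 45 gene lists, with filled points for a camera adjusted p under 0.05 and open points for the others. Neuroendocrine markers lie at 3.39, against 1.01 in the FPKM values with their own filter and a pseudocount of 1. Ribosomal protein genes lie at −1.63, against −0.57 without control 3.

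Lists tied to exercise physiology and tumor growth were not called at the settings used here, and several of their members had large mean differences. Among exercise-regulated secreted factors (median 0.23, camera adjusted p = 0.905), 1 was higher and 2 lower adjusted over the list alone. Fndc5, the precursor of the myokine irisin, was at 2718 to 3972 in controls and at 226, 2966, 116, 718 and 586 in exercise tumors. As for the ventral prostate gene Sbp, exercise 2 lay within the control range and the other exercise tumors below it. Metrnl was at 1158 ± 767 and 379 ± 104, and the chemokine Cxcl12 at 312 ± 108 and 1095 ± 563. The IGF and insulin axis had a median of 0.55 (adjusted p = 0.0925), and was called as higher with the length trend removed (0.75, 0.0304) and with library weights (1.03, 0.0209). Its binding proteins Igfbp3 and Igfbp5 were at 358 ± 62.2 and 1268 ± 564, and at 3870 ± 2867 and 11604 ± 4952. Androgen-responsive genes (median 0.32, adjusted p = 0.831, and 0.15 with 0.879 without control 3) included Tgm4, a transglutaminase of seminal fluid, at 143 to 184 in controls and at 134453, 430, 925590, 71228 and 4253 in exercise tumors. They also included Slc45a3, at 19685 ± 3801 and 8933 ± 7075. Proliferation genes had a median of 0.12 (adjusted p = 0.905, and 0.06 with 0.867 without control 3). Of the 35 members 21 had a higher and 14 a lower mean. E2f1 and Cdk1, named for their small p, were among the lower, at 288 ± 45.9 and 158 ± 84.5, and at 340 ± 112 and 221 ± 29.8. For p53 and senescence genes the median was 0.07, the mean −0.13 and camera's direction lower (adjusted p = 0.353), and the median was −0.23 without control 3 (0.0751) and −0.03 without exercise 2. In that list the cell cycle inhibitor genes Cdkn2a and Cdkn2b were at 1389 ± 1216 and 163 ± 122, and at 481 ± 126 and 201 ± 83.8. Camera's direction was lower for proliferation, glucocorticoid-responsive and immediate early genes, although their medians and means were above 0.

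The remaining lists were not called by camera at the settings used here, but some were with a tumor left out or under another setting. Lipogenesis genes had a median log2 fold change of 0.67 (adjusted p = 0.0581) and circadian clock genes one of 0.61 (0.0925). The lipogenesis list was called as higher without control 4 (0.86, 0.0382), without exercise 2 (0.68, 0.0231), over genes with a mean of at least 50 (0.65, 0.0421), with the length trend removed (0.74, 0.0395) and with library weights (0.73, 0.0144). The clock list was called as higher without control 1 (0.72, 0.0447), without exercise 5 (0.69, 0.0369), over genes with a mean of at least 50 (0.65, 0.0410) and in the FPKM values (0.46, 0.0378). Hypoxia response genes were at −0.22 (0.268), FoxO and PI3K feedback genes at 0.12 (0.942), and mitochondrial biogenesis and fatty acid oxidation genes at 0.14 (0.769). Medians were −0.34 for the unfolded protein response (0.249), −0.19 for the oxidative stress response (0.249) and 0.07 for heat shock genes (0.914). The unfolded protein response was called as lower without exercise 3 (−0.54, 0.0360). Immediate early genes were at 0.50 (0.942) and glucocorticoid-responsive genes at 0.14 (0.859), medians that turned to −0.08 (0.545) and −0.17 (0.771) without control 3. Without that tumor the FoxO list was at 0.0057 (0.709), the mitochondrial list at 0.06 (0.826), the unfolded protein list at −0.22 (0.219) and the clock list at 0.39 (0.146). With each tumor left out in turn, 28 of the 31 lists not called had a median that changed sign or moved over 1.5 times at least once, and 9 changed sign. Of the markers of other tissues, skeletal muscle was at 1.46 (0.143), adipocytes at −0.50 (0.183), red blood cells at −0.64 (0.515, and −0.0064 with 0.928 without control 3) and urothelium at 1.30 (0.255). Skeletal muscle markers were called as higher without control 3 (2.54, 2.73e-04), without exercise 2 (2.16, 0.0380), with the length trend removed (1.75, 0.0395) and with library weights (3.78, 7.47e-05). Urothelial markers were called as higher with library weights (1.92, 0.0168) and with the replicate number as a block (1.38, 0.0178). Adipocyte markers were called as lower without control 3 (−1.38, 0.0124), without exercise 5 (−0.55, 0.0378) and with that block (−0.55, 0.0136). The mean level of the skeletal muscle list was 8.89 in control 3, 10.6 in exercise 1 and 7.95 in exercise 4, against 3.47 to 5.59 in the other tumors. Adjusted over the list alone, the members that passed were 6 higher and 1 lower in lipogenesis, 3 higher and 1 lower in the circadian clock, 1 higher and 2 lower in hypoxia, and 2 lower in FoxO and PI3K feedback. They were 2 lower in p53 and senescence, 1 lower in mitochondrial biogenesis, 1 lower in neutrophils, 2 higher in mast cells, and 1 higher and 1 lower in urothelium. No member passed in the other lists not called, apart from the secretory, macrophage and exercise-regulated lists given above.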

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

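The tests in this part were written before their results were seen, but removal of the length trend was added to the analysis after seeing the data. Within each group, the highest or lowest tumor was compared with the gap rule of Dixon for 220 series of values, where about 1 in 20, or 11, stand apart by chance, and 21 did. In 4 of the 21 the other controls were tied, so that any other value would stand apart. The series are not independent, since lists stand beside their own members and named genes were picked by p in these data. The 21 is therefore no measured excess over chance.

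Exercise 2 accounts for 11 of the 21. On the log2(normalized count + 1) scale it was lowest of the exercise tumors for Ascl1 (2, the others at least 5.09), Clu (15.9, the others at least 17.6), Igfbp3 (8.43), Krt4 (10.2) and Sema3c (8.34). It was highest for Cldn3 (12.9) and Scgb2b15 (8.24, the others at most 1.58). Its mean list levels were lowest for Pten-null luminal progenitor-like markers (10.3), dendritic cell markers (4.79), mast cell and eosinophil markers (3.82) and neuroendocrine markers (3.47). Whether the group label of this tumor is right stays open, as no test of it was run, and with it what the 1343 genes called without exercise 2 mean. Control 4 was highest of the controls for Ascl1 (2), Nefl (2.81) and Snap25 (3.17), from counts of 3, 6 and 8 with the other controls tied at 0, and for the p53 and senescence list (9.34). Control 1 was lowest for the glycolysis list (11.8, the others 12.1). Exercise 3 was highest of its group for oxidative phosphorylation (11.9) and ribosomal protein genes (14.4). Control 3 stood apart in total normalized counts (102248000, or 102.2 on a scale of 1e6), in C1rb (2.32, a normalized count of 4 or about 1 read, with the others tied at 1) and in the skeletal muscle list (8.89, the others at most 3.71).

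Control 3 also held ribosomal protein genes at a median 4.27 on the log2 scale above the other controls, with an SD of 0.50 over the 32 members. Scaling by a few dominant genes was weighed by the median of all tested genes, which was −0.03, with the list 4.30 beyond it. A scale factor moves all genes alike, so it does not set the list apart from other genes. As the deposited values were already scaled, with upper quartiles of 614 to 657, a small median was to be expected. How much the scaling of control 3, where 1 read is worth 3.79, adds to the 4.27 was not tested. A trend with transcript length is present in this library, with median deviations from 0.51 in the length quartile with the shortest transcripts to −0.66 in that with the longest. After its removal the list still lay 3.46 above the other controls, a share of 0.810 of the first value. The trend in the lengths used is thus argued against as the whole cause, while it may account for the rest. These lengths are medians over all transcripts of a gene, such as 2093 for Ttn. They may miss part of a length trend, so length itself stays open. RNA quality, library handling and a difference between animals stay open, and no biological explanation was tested.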

How the results depend on the processing

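The library weights and the length and GC trend removals were chosen after seeing the data. The count of 0 genes past adjusted p in limma stood in all alternatives but 2: leaving out tumors gave 0 to 1343 (the latter without exercise 2), and library weights gave 9661. The weights did not converge and ran from 0.0671 for control 3 to 8.48 for exercise 4, so that fit leans on few libraries. The count at an unadjusted p under 0.05, 4087, ran from 2221 (without control 2) to 6046 (without control 4), and was 2290, 2386 and 2680 without exercise 1, 4 and 5. It was 10258 with library weights and 2680 for the 8 tumors that share replicate numbers, the same fit as without exercise 5. With the replicate number as a block, these 8 tumors gave 0 genes past adjusted p, 4497 at an unadjusted p and 16 lists. The labels give no shared litter or day, and deviations of same-numbered tumors correlated at −0.08, 0.22, 0.36 and 0.44, with 5 of the 8 correlating best with their own number, a hint from the data. As the tumors numbered 1 did not deviate together, the numbers were not taken to pair the tumors. Of lists not called with all 9 tumors, the block called urothelial markers (1.38, 0.0178) and adipocyte markers (−0.55, 0.0136), and the same 8 tumors without it interferon, adipocyte and clock genes. The 14 called lists became 12 to 18 with a tumor left out, 26 with library weights, 19 with the length trend removed, 0 with an estimated correlation and 0 by the directional fry test, while 15 lists passed fry's mixed test for change in either direction, 10 of them among the 14. Length removal added the progenitor-like, mast cell, skeletal muscle, lipogenesis and IGF lists. Lists not called with all tumors that were called with 1 left out were the progenitor-like, mast cell, skeletal muscle, adipocyte, lipogenesis, clock, unfolded protein and interferon lists. In the FPKM values the mast cell and clock lists were called too, and the progenitor-like list with a pseudocount of 1 only. In 21 refits 10 of the 14 lists were called in the same direction each time, and the others 11 (luminal), 16 (dendritic), 19 (Wnt, Hippo and Notch) and 20 times (cholesterol). With the FPKM filter and pseudocounts of 1 and 0.1, medians were 0.87 and 1.79 for the nerve and 0.83 and 1.28 for the endothelial list. Pten's log2 fold change of 0.34 ran from 0.25 to 0.42 with a tumor left out. It was 0.25 with library weights, now past the threshold (adjusted p = 0.0196, over all alternatives 0.0196 to 0.590), and −0.24 once the length trend was removed. The cause of these shifts was not tested. No other named gene turned its direction; 47 of 59 passed without exercise 2 and 59 with library weights. Upper-quartile scaling moved the median of all genes from 0.08 to 0.15, and the higher share at an unadjusted p went from 57.8% to 47.5% and 46.1% in the FPKM values with pseudocounts of 1 and 0.1. The planned count-model tests, voom weights and prior count were not run because the values are normalized. Depth is known only as an estimate, and 1 read is worth 3.79 in control 3, so low genes such as Ascl1 are coarsest there.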

Other observations

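The tests of the seminal vesicle pattern, that of the epithelial share and removal of the length trend were chosen after results were seen, and so were the genes of this paragraph. Ren1, the renin gene, had a normalized count of 143787 in exercise 3, 5575 in exercise 1 and 2259 in exercise 4, and 30 or less in the other tumors. Scgb1b20, of the androgen-binding protein family, was at 13893 to 326242 in controls and at 14570 in exercise 2, 1184 in exercise 4 and 9 or less in exercise 1, 3 and 5. Members of this family are near-identical, so single counts are uncertain.

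Homeobox genes were also looked at after seeing the values, with no test of them as a group, and none passed limma's adjusted threshold (smallest adjusted p 0.130). Of 11 tested Hox genes of paralog groups 9 to 13, 6 were higher and 1 lower at an unadjusted p under 0.05, and of 14 in groups 1 to 8, 8 were higher and 0 lower, where 4087 of all 14818 genes reached that level. Hoxd13 was at 66.0 ± 10.3 (SD, n = 4) in controls and 326 ± 212 (SD, n = 5) in exercise tumors, and Hoxd10 at 19.0 ± 10.1 and 63.0 ± 28.8. The lower gene was Hoxb13.

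Seminal vesicle genes stood far above the control level in exercise 1, 3 and 4. A response shared by all exercise tumors was not seen. In 2 of the 5, exercise 2 at 2.13 and exercise 5 at 2.04, the list mean lay below the highest control, at 2.50. This restates the pattern, which was seen first, and is no separate test of it. The group label of exercise 2 is also untested. Carry-over of 1 tissue of fixed composition is argued against for exercise 4, whose log2 ratio over the 11 list members had an SD of 3.05 against exercise 1 and 2.48 against exercise 3. Between exercise 1 and 3 the SD was 1.26, which leaves it open for these tumors. A hypothesis that stays open is that the samples hold different lobes or accessory glands. Of the 20 tested genes with the widest range over the tumors, 8 belong to the secretory and seminal vesicle lists. Seminal vesicle genes that did not pass the filter, such as Svs1 at 286508 in exercise 1, are not in that count. The labels name no lobe, so different lobes or glands cannot be told apart from an effect in some of the exercise tumors.

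The second pattern is the higher level of 6 stromal, neural and basal lists in exercise tumors (smooth muscle, endothelial, nerve, fibroblast, neuroendocrine and basal). Control 3 alone is argued against, as 6 of the 6 lists were called without it. After removal of the length trend 6 of the 6 were called too. This argues against the trend in the lengths used, but not against one that these median lengths miss. These are calls at camera's preset correlation, and with all 9 tumors each list had adjusted p = 0.763 with an estimated correlation. A lower epithelial share that raises all other cell types alike is not decided. Over all 13 stromal and immune cell lists, called or not, the group difference in list level ran from −0.46 (adipocytes) to 2.29 (nerve). Its variance over the lists was as large in 4 of the 126 splits of the tumors (exact permutation p = 0.0317), although the gap between the 5 stromal and 8 immune lists alone gave p = 0.0714. Unequal shifts go against a uniform rise only if each list is specific to its cell type, and the test was not repeated without control 3. A lower epithelial share, an effect of running and a different sampled region of the gland stay open. For the sampled region, the smooth muscle, nerve, neuroendocrine and basal lists were each highest in exercise 1, 3 and 4, the tumors with seminal vesicle genes. Exercise 5 was close behind in some, as in the basal list at 8.71 against 8.95 in exercise 3, and in the neuroendocrine list at 6.07 against 6.39. The fibroblast and endothelial lists did not follow this, at 8.70 and 7.27 in exercise 3 against 10.3 and 7.90 in exercise 5.

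For the counts themselves, 100 splits of the 9 tumors into 4 and 5 were drawn, the real one included. At an unadjusted p under 0.05, 3 of the 100 gave at least the 4087 genes of the real split, with 5595 the highest of the others. Few splits gave such a count, but it was 1 of 3 counts compared and other splits exceeded it. A group effect is therefore not established by it. The highest split exchanged control 4 with exercise 3, and another, with 4705 genes, exchanged control 4 with exercise 2. For gene lists, 44 of 100 splits gave at least the 14 of the real split, up to 24, so chance is not excluded as the source of that count. For genes past adjusted p the real split gave 0, so all 100 gave as many by construction and the comparison tells nothing about chance. The highest count, 239, came from the real split with control 3 and exercise 2 exchanged. Such a count may point to a structure of the samples, for which no test was run.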
